A study of Mus musculus with 7 samples.

How the data were processed

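The samples were GFP-positive adrenal cells of C57BL/6J mice carrying either an Sf1:eGFP transgene (SF1+, 4 arrays) or a TCF/Lef:H2B-GFP transgene (Wnt+, 3 arrays). Per the labels' protocols, adrenals of 6-week-old males were pooled (10 per sort), digested with collagenase, sorted for viable GFP-positive cells, and 5 ng of total RNA per sort was amplified with a whole-transcriptome kit and hybridised to Mouse Gene ST strip arrays. The labels state 4 independent sorts per genotype, of which 3 were analysed here for Wnt+. Groups and replicate numbers came from the sample titles.

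The authors deposited log2 expression values per transcript cluster. Per the file headers and the submitters' processing notes these were made with the robust multi-array average (RMA, in the oligo package) on perfect-match probes, which corrects background, quantile-normalises between arrays and summarises the probes of a cluster, and the software versions are not given in the sources used here. RMA draws all arrays to the same distribution, so a change in total RNA per cell cannot be seen, and differences of dim genes are compressed near the floor of the values. The authors' deposited table also holds, per the file headers, an unadjusted p-value of a t-test of the groups and a linear fold change (Wnt+ over SF1+) for each cluster. Recomputing them from the log2 values gave the same folds within 4.88e-09 on the log2 scale and the same p-values within 5.98e-08 for a test with pooled variance. The same table holds the authors' fold and paired p-value for another experiment, which its header describes as Bio against vehicle in mouse adrenocortical tumor cell lines. Its sample values were not analysed here, and 7 per-sample columns of a sheet used for drawing were not used.

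Of 28944 transcript clusters, 23812 had a gene symbol in the file and 5132 had none and were left out. Entrez identifiers of 23508 clusters matched a RefSeq gene table (assembly GRCm38.p6), used for current symbols, which renamed 1875 genes, and for the order of the genes around Nr5a1. No coordinates are given because the files name no genome build. Each gene was represented by its cluster with the highest mean over the 7 arrays, which left 20719 genes, and 6 of these shared all values with another gene. No filter on dim genes was applied, and no arrays were identical.

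Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient for the group, prior degrees of freedom 1.98) and adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Standard errors are those of the moderated fit. All tests were two-sided. Before the data were examined, the sample groups, the tests, the alternatives, 27 gene lists and the rule for named genes were fixed. The rule named the 12 largest rises and the 12 largest falls among genes past the threshold whose arrays did not overlap between the groups, leaving out predicted genes, unnamed clones and olfactory or vomeronasal receptors, and up to 8 members per list chosen by the smallest p or by textbook role. Only 11 genes rose, so all are named. Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists, and each list's members were also counted after adjustment over the list alone. A list score is the mean log2 value of its members in an array, compared by an exact permutation test over the 35 splits of 7 arrays into 3 and 4.

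The alternatives were a replicate block, leaving out each array, leaving out dim genes, median-centring, a further quantile normalisation, array quality weights, trended and robust moderation, no moderation, the mean of a gene's clusters, all transcript clusters, a threshold of 0.01, a minimum log2 change of 0.5 (treat), the authors' p-values after adjustment, camera with an estimated correlation, and fry. Leaving out both arrays nearest the other group, leaving out the members of endothelial, immune and interferon lists, and 4 further lists (plasmacytoid dendritic, natural killer and B cell markers, and interferon-stimulated genes) were added after the data were seen. The added lists were adjusted together with the 27 fixed lists where a camera p with an estimated correlation is given for them. The scripts were tested on 20 simulated data sets of 4 against 3 arrays and 20719 genes with 200 changed: 72.2% of genes changed by 1 on the log2 scale and 94.1% of those changed by 2 were called, with 5.45% false calls, and a list of 25 genes shifted by 0.5 was called in 20 of 20 sets and an unshifted list in 2 of 20. Noise in these sets was drawn independently for each gene, with no correlation between genes and no aberrant array. The rates hold for that setting and need not hold for the real arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.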

Results

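Gene expression was measured on Affymetrix mouse gene arrays in GFP-positive adrenal cells that had been collected by flow cytometry from 6-week-old male mice of 2 reporter strains. In the SF1+ group (4 arrays), GFP was driven by a genomic fragment of Nr5a1, which encodes the steroidogenic transcription factor SF1. In the Wnt+ group (3 arrays), a nuclear histone-GFP fusion was driven by multimerised TCF/Lef binding sites, which read canonical Wnt/beta-catenin signalling. Each array held RNA from an independent sort of 10 adrenals. The comparison asked which genes distinguish adrenal cells sorted on the Wnt reporter from those sorted on the SF1 reporter. Each group came from its own transgenic line. Effects of the line or its reporter therefore cannot be told apart from those of the cell population. All differences are given as Wnt+ minus SF1+ on the log2 scale. The median log2 value per array lay between 2.92 and 3.02, and the number of arrays limits the precision. Pearson's r between arrays was taken over 20719 genes, which are not independent replicates. It was 0.972 to 0.983 in the 6 pairs within SF1+, 0.962 to 0.968 in the 3 pairs within Wnt+ and 0.926 to 0.969 in the 12 pairs across groups. The first principal component held 46.6% of the variance and had all 4 SF1+ arrays on one side and all 3 Wnt+ arrays on the other.

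The genes behind the sort gates were examined first. Nr5a1 itself was not higher in the libraries sorted on its reporter. Its mean log2 value was 5.75 ± 0.47 (SD, n = 4) in the libraries labelled SF1+ and 7.30 ± 0.38 (SD, n = 3) in those labelled Wnt+. The difference of 1.55 (SE 0.29) had every Wnt+ array above every SF1+ array and missed the threshold over all genes (limma adjusted p = 0.0938). Axin2, a feedback inhibitor and standard target of the Wnt pathway, differed by 0.67 (SE 0.41, limma adjusted p = 0.50), with 4.16 ± 0.49 (SD, n = 4) in SF1+ and 4.83 ± 0.77 (SD, n = 3) in Wnt+. With each array left out in turn, the Axin2 difference ranged from 0.27 to 1.05. Lef1, a target and a transcription factor of the same pathway, differed by 0.22 (SE 0.15, limma adjusted p = 0.558). The gene whose minimal promoter is part of the Wnt reporter, Hspa1b, had no value under its symbol. The group names below are those of the labels, and the directions rest on them although Nr5a1 ran against its own label.

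Among the genes past the threshold, Wnt+ libraries had higher expression of Mrap, Alas1 and Fasn and lower expression of the lymphoid gene Nkg7, the dendritic cell gene Siglech and the interferon regulatory factor Irf7. Mrap, the accessory protein that carries the ACTH receptor to the cell surface, rose by 1.68 (SE 0.18, limma adjusted p = 0.0396), from 5.28 ± 0.07 (SD, n = 4) to 6.96 ± 0.41 (SD, n = 3). Siglech, a surface lectin of plasmacytoid dendritic cells, had the smallest p of all genes and fell by 3.24 (SE 0.14, limma adjusted p = 0.00123), from 6.55 ± 0.19 (SD, n = 4) to 3.31 ± 0.17 (SD, n = 3). In all, 53 of 20719 genes passed an adjusted p of 0.05, of which 11 were higher and 42 lower in Wnt+. At least 2-fold differences were found for 38 of them (8 higher, 30 lower). At an unadjusted p under 0.05 there were 3211 genes (1576 higher, 1635 lower) against 1036 from chance alone. The arrays of the groups did not overlap for any of the 53 genes, nor for 2922 genes in all (14.1%, against 5.71% by chance). The count depended on single libraries. It was 312 without Wnt+ replicate 1 and 76 without SF1+ replicate 1 (23 higher instead of 11). It was 8 without Wnt+ replicate 2, 3 without SF1+ replicate 4, 2 without Wnt+ replicate 3, and 1 without SF1+ replicate 2 or replicate 3. Members of the endothelial, immune and interferon lists made up 15 of the 53 genes, by a choice of lists made after the data were seen. With all list members left out, 4 of the other 38 passed (limma adjusted p of 0.0327 to 0.0673 for the 38). The log2 fold changes of these 38 stayed the same, while the moderation and the adjustment were both refitted.

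**Figure D1:**
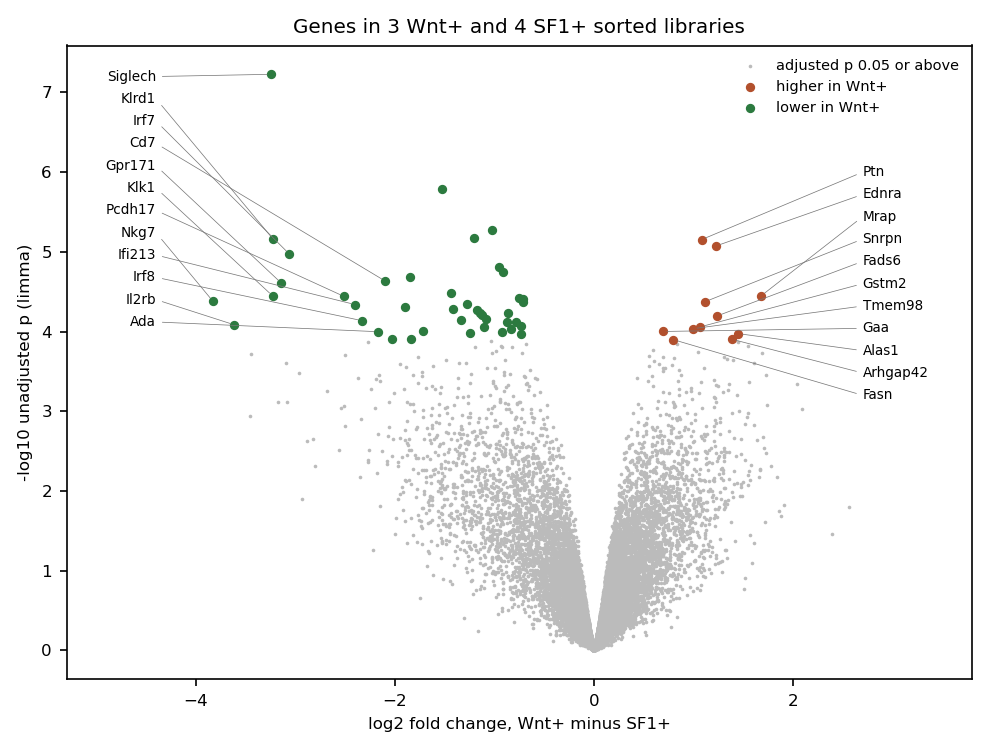
Each point is 1 of 20719 genes, with the log2 fold change (Wnt+ minus SF1+) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 11 coloured genes on the right and 42 on the left had an adjusted p under 0.05, and Siglech stands highest, with a log2 fold change of -3.24.

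The 11 genes that rose were all named genes. Alas1, the first enzyme of heme synthesis, rose by 1.45 (SE 0.19) to 9.13 ± 0.04 (SD, n = 3). The others besides Mrap were Arhgap42 (1.39), the fatty acid desaturase family member Fads6 (1.24), the endothelin receptor Ednra (1.23), the imprinted gene Snrpn (1.12) and the secreted growth factor Ptn (1.08). They further included the glutathione transferase Gstm2 (1.07), Tmem98 (1.00), the fatty acid synthase Fasn (0.80) and the lysosomal alpha-glucosidase Gaa (0.69). Their limma adjusted p lay between 0.0243 for Ptn and 0.0495 for Arhgap42 and Fasn.

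Lymphocyte markers were among the genes with the largest falls. Nkg7, a cytotoxic granule protein, fell by 3.83 (SE 0.42, limma adjusted p = 0.0396), from 6.73 ± 0.83 (SD, n = 4) to 2.90 ± 0.05 (SD, n = 3). Il2rb, an interleukin-2 receptor chain, fell by 3.61 (SE 0.44), the killer cell lectin-like receptor Klrd1 fell by 3.23 (SE 0.27), and Cd7 fell by 2.10 (SE 0.21). In Wnt+ Nkg7 (2.90), Il2rb (2.99), Klrd1 (2.38), Cd7 (2.94) and the kallikrein Klk1 (2.55) lay near or below the array medians, a range where differences are compressed, so the size and order of these falls are uncertain. The remaining large falls were those of Klk1 (-3.23), the G protein-coupled receptor Gpr171 (-3.14) and the interferon regulatory factor Irf7 (-3.06). They were followed by the protocadherin Pcdh17 (-2.51), the interferon-inducible Ifi213 (-2.40, listed in the file as Pydc4), the interferon regulatory factor Irf8 (-2.33) and the adenosine deaminase Ada (-2.17). Of the 16 measured lymphocyte markers, 10 fell when adjusted over the list alone. Of these, 2 also passed over all genes, Nkg7 and Lck (-0.95), a T-cell kinase. Gzma, a granzyme, differed by -3.44 (adjusted p over the list alone = 0.00101, over all genes 0.0561). The list median was -1.11 (camera adjusted p = 1.52e-10, and adjusted p = 0.285 with an estimated correlation).

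Genes of steroid synthesis were higher in Wnt+ as a group by camera with its preset correlation, but not with an estimated one. Of 20 steroidogenic enzymes and cofactors, 10 rose when adjusted over the list alone and none fell. Over all genes tested with limma, 0 passed and 10 had an unadjusted p under 0.05. Cyp11b1, which makes corticosterone, was higher by 1.69 (SE 0.24, adjusted p over the list alone = 0.00374, over all genes 0.0561). It was at 7.36 ± 0.42 (SD, n = 4) in SF1+ and 9.05 ± 0.20 (SD, n = 3) in Wnt+. Cyp11b2, the aldosterone synthase, was higher by 1.31 (SE 0.31), and Star, which carries cholesterol into mitochondria, by 1.03 (SE 0.24). Cyp11a1, the side-chain cleavage enzyme, was higher by 1.00 (SE 0.20), Cyp21a1, the steroid hydroxylase, by 1.30 (SE 0.36), and Hsd3b1 by 0.71 (SE 0.17). Each of these passed the list-alone threshold. Cyp17a1, which the adult mouse adrenal cortex hardly expresses, was near the lower end of the arrays' values in both groups, at 2.25 ± 0.13 (SD, n = 4) and 2.12 ± 0.09 (SD, n = 3). The list median was 0.70 (camera adjusted p = 1.42e-04, and adjusted p = 0.285 with an estimated correlation).

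Markers of both main cortical zones were higher in Wnt+ by the same test, and again not with an estimated correlation. Of 24 zona glomerulosa markers, 12 rose when adjusted over the list alone and 0 over all genes with limma (13 at an unadjusted p under 0.05). Their median was 0.66 (camera adjusted p = 4.89e-06, and adjusted p = 0.285 with an estimated correlation). Among them the calcium channel gene Cacna1h was higher by 1.48, Rgs4 by 1.35, and the signalling ligands Wnt4 by 1.07 and Shh by 0.88. The potassium channel gene Kcnk3 was higher by 0.99 and Dab2 by 0.61, and all of these passed the list-alone threshold. Of 16 zona fasciculata markers, 8 rose when adjusted over the list alone and Mrap alone over all genes. Their median was 0.66 (camera adjusted p = 4.58e-08, and adjusted p = 0.285 with an estimated correlation). Akr1b7, an aldose reductase-like protein under ACTH control, was higher by 0.79 (SE 0.12, adjusted p over the list alone = 0.00139), Soat1, which esterifies cholesterol, by 0.99, and Scarb1, the lipoprotein receptor, by 0.65. Of 24 genes of ACTH and cAMP signalling, 5 rose and 1 (Creb1, -0.51) fell when adjusted over the list alone (camera adjusted p = 0.0188, and adjusted p = 0.379 with an estimated correlation). The ACTH receptor Mc2r differed by 0.84 (adjusted p over the list alone = 0.0777). Of 20 adrenocortical transcription factors, 3 were higher and 2 lower when adjusted over the list alone. The former were Nr5a1 (1.55), Gata6 (0.78) and Hoxb9 (1.06), and Nr5a2 (-0.76) was among the latter. Nr0b1 differed by 0.85 (SE 0.63), which rested on Wnt+ replicate 2 (3.42, 5.49 and 2.50 in Wnt+ replicates 1, 2 and 3, with an SF1+ mean of 2.95). The list as a whole had a camera adjusted p of 0.463. In the same libraries, endothelial and lymphoid markers were lower and chromaffin markers higher in Wnt+, as given with those lists.

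**Figure D2:**
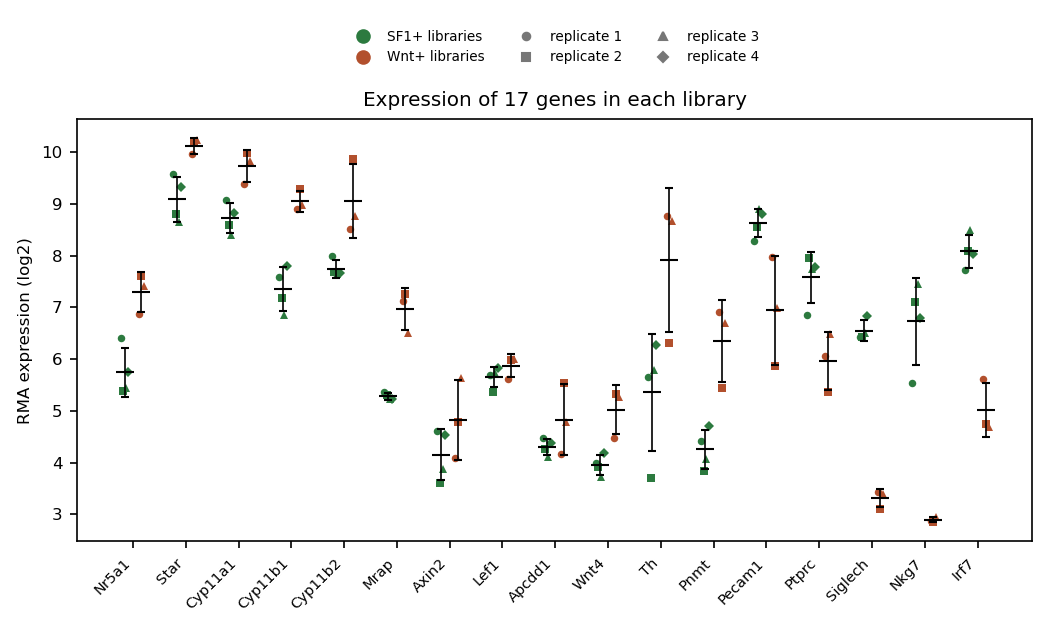
Points give the RMA expression (log2, vertical axis) of 17 genes in each library, with SF1+ in green, Wnt+ in orange and the symbol giving the replicate number; horizontal bars are group means and error bars 1 SD (n = 4 and n = 3). Nr5a1 and Star lie higher in the 3 Wnt+ libraries, Axin2 and Lef1 overlap between the groups, and Siglech (6.55 against 3.31) and Nkg7 (6.73 against 2.90) lie lower in Wnt+.

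Targets of the Wnt pathway differed little between the groups gene by gene. Of 35 Wnt/beta-catenin target genes, 0 passed over all genes with limma and 0 when adjusted over the list alone, while 5 were higher and 0 lower at an unadjusted p under 0.05. The values of Prox1 (0.92, SE 0.30), Nkd1 (0.80, SE 0.26), Lgr5 (0.75, SE 0.30), Tnfrsf19 (0.61, SE 0.17) and Apcdd1 (0.53, SE 0.30) had limma adjusted p of 0.168 to 0.465, and that of Apcdd1 was 0.18 without Wnt+ replicate 2. The list median was 0.15. The mean of its members was 3.79 ± 0.05 (SD, n = 4) in SF1+ and 3.98 ± 0.04 (SD, n = 3) in Wnt+ (camera adjusted p = 0.0305, and adjusted p = 0.285 with an estimated correlation). That call also ended without SF1+ replicate 2 (camera adjusted p = 0.0585, in a range of 0.0251 to 0.0585 over the arrays left out in turn). Of 43 Wnt ligands, receptors and secreted modulators, 0 passed either threshold with limma, and 10 were higher and 1 lower at an unadjusted p under 0.05. The list median was 0.12 (camera adjusted p = 0.0279, and adjusted p = 0.285 with an estimated correlation). Its call ended without SF1+ replicate 1 (camera adjusted p = 0.0567), Wnt+ replicate 1 (0.0504) or Wnt+ replicate 3 (0.135). Within it the R-spondin receptor gene Lgr4 differed by 1.58 (SE 0.39), the co-receptor gene Lrp6 by 0.70 (SE 0.17), Ccdc80 by 0.59 (SE 0.20) and the capsular ligand Rspo3 by -0.22 (SE 0.21). In hedgehog signalling, 1 of 17 genes, Shh, rose when adjusted over the list alone (0.88, SE 0.20). Gli1, which marks capsular cells that receive the signal, differed by 0.07 (SE 0.11), and the hedgehog list had a camera adjusted p of 0.0791. With arrays left out in turn the camera adjusted p was 0.0177 to 0.377, and the list passed only without Wnt+ replicate 2.

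Several markers of other cell types differed between the sorts. All 25 endothelial markers had a negative difference, and 20 fell when adjusted over the list alone. Over all genes with limma 0 passed (21 at an unadjusted p under 0.05). The median was -1.44 (camera adjusted p = 8.91e-13, and adjusted p = 0.379 with an estimated correlation). Pecam1, an endothelial adhesion molecule, was at 8.63 ± 0.28 (SD, n = 4) in SF1+ and 6.94 ± 1.05 (SD, n = 3) in Wnt+, and Cdh5, the vascular cadherin, differed by -1.48 (SE 0.41). The endothelial mean ranged from 5.21 to 7.14 among the 3 Wnt+ libraries and from 7.29 to 7.81 among the 4 SF1+ libraries. Its difference of -1.33 shrank to -0.80 without Wnt+ replicate 2, so the size of the fall rested in part on that library. Of 23 chromaffin markers, 4 rose when adjusted over the list alone and 0 over all genes with limma (9 at an unadjusted p under 0.05). The median was 0.82 (camera adjusted p = 4.58e-08, and adjusted p = 0.379 with an estimated correlation). Pnmt, the adrenaline-forming enzyme, was higher by 2.09 (SE 0.38, adjusted p over the list alone = 0.0213), Npy by 1.73 (SE 0.40) and Scg2 by 1.41 (SE 0.36). Th, the first enzyme of catecholamine synthesis, differed by 2.56 (SE 0.81, adjusted p over the list alone = 0.0517). Of 25 macrophage and myeloid markers, 2 fell when adjusted over the list alone, the leukocyte antigen genes Ptprc (-1.61) and Cd52 (-1.54). The list median was -0.33 (camera adjusted p = 4.32e-04, and adjusted p = 0.515 with an estimated correlation), and its call ended without SF1+ replicate 2 (camera adjusted p = 0.0766). None of 17 Schwann and sustentacular markers passed when adjusted over the list alone (3 higher at an unadjusted limma p under 0.05). Their median was 0.09 (camera adjusted p = 0.0482, and adjusted p = 0.407 with an estimated correlation). That call ended with 5 of the 7 arrays left out in turn (camera adjusted p of 0.0107 to 0.291). None of 25 capsule and fibroblast markers passed when adjusted over the list alone, where limma had 2 higher and 2 lower at an unadjusted p under 0.05. Col1a1 differed by 0.51 (SE 0.29), and the capsule list had a camera adjusted p of 0.143. With arrays left out in turn, this list passed only without Wnt+ replicate 2 (camera adjusted p = 1.18e-05). Its mean difference was 0.24, and it was 0.59 without that replicate and 0.04 without Wnt+ replicate 1. No member of the X-zone (8 genes), erythroid (11) or adipocyte and hepatocyte (14) lists passed when adjusted over the list alone. At an unadjusted p under 0.05, limma had 1, 0 and 1 of them higher and 0, 0 and 2 lower. The camera adjusted p were 0.135, 0.831 and 0.877. With arrays left out in turn, the X-zone list passed only without Wnt+ replicate 3 (camera adjusted p = 0.0122). Akr1c18, the X-zone enzyme, was at 2.02 ± 0.11 (SD, n = 4) and 2.14 ± 0.16 (SD, n = 3).

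**Figure D3:**
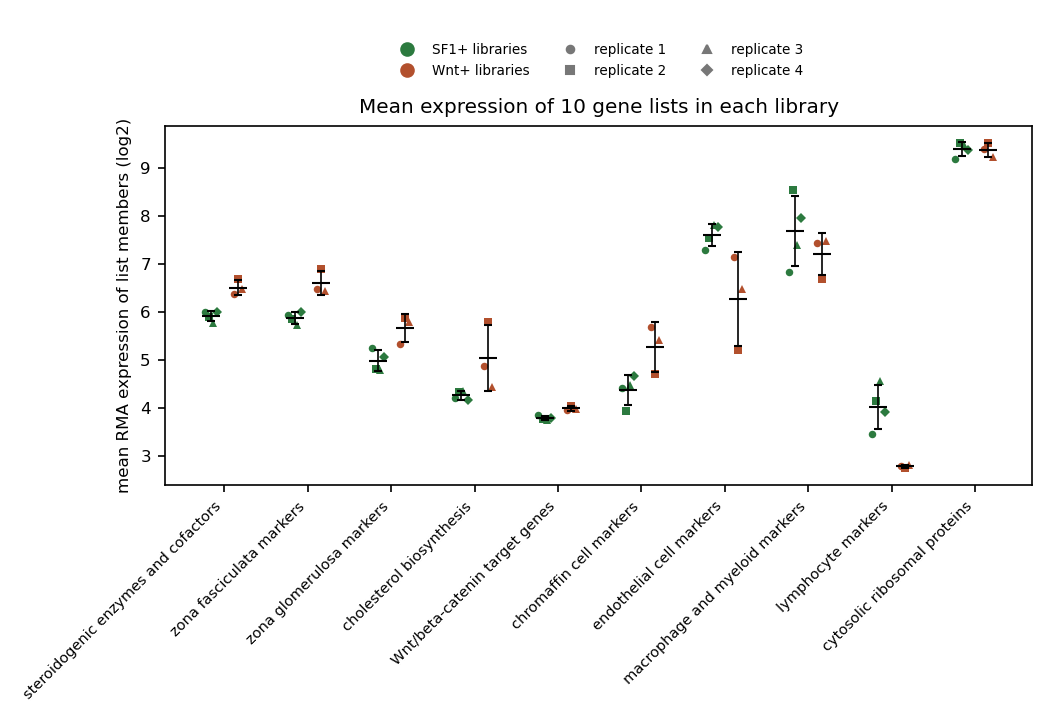
Points give the mean RMA expression (log2, vertical axis) of the members of 10 gene lists in each library, with SF1+ in green, Wnt+ in orange and the symbol giving the replicate number; horizontal bars are group means and error bars 1 SD (n = 4 and n = 3). The steroidogenic, zona fasciculata, zona glomerulosa and chromaffin means lie higher in the 3 Wnt+ libraries, the endothelial and lymphocyte means lie lower, and the ribosomal protein mean differs by -0.01.

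Genes of cholesterol biosynthesis were mostly higher in Wnt+. Of 23 genes of cholesterol biosynthesis, 22 had a positive difference and 9 an unadjusted p under 0.05. Dhcr7, the last enzyme of the pathway, was the 1 gene that rose when adjusted over the list alone (1.73, SE 0.27). Their median was 0.72 (camera adjusted p = 2.05e-06, and adjusted p = 0.407 with an estimated correlation). The mean of these genes was 4.88, 5.80 and 4.44 in Wnt+ replicates 1, 2 and 3 and 4.16 to 4.35 in the SF1+ libraries. Its difference was 0.77, and it was 0.39 without Wnt+ replicate 2 and 1.07 without replicate 3. Of 21 genes of cholesterol uptake, storage and trafficking, 1 (Soat1) rose and 1 (Stard5, -0.90) fell when adjusted over the list alone (camera adjusted p = 0.0791). Of 33 oxidative phosphorylation subunits, 32 had a positive difference and 0 passed when adjusted over the list alone (11 higher at an unadjusted limma p under 0.05). The median was 0.32 (camera adjusted p = 4.89e-06, and adjusted p = 0.464 with an estimated correlation). The mean of these genes was 7.51, 8.04 and 7.31 in Wnt+ replicates 1, 2 and 3 and 7.08 to 7.41 in the SF1+ libraries (exact permutation p = 0.143). Its difference of 0.33 fell to 0.12 without Wnt+ replicate 2, so it rested largely on that library. Of 26 genes of glutathione and antioxidant defence, 2 rose when adjusted over the list alone, the mitochondrial peroxiredoxin Prdx3 (1.20) and Gstm1 (0.59). The median was 0.25 (camera adjusted p = 3.56e-04, and adjusted p = 0.407 with an estimated correlation). The mean of the list was 6.86, 7.21 and 6.57 in the same Wnt+ replicates and 6.39 to 6.68 in SF1+ (exact permutation p = 0.0857), and its difference of 0.39 fell to 0.23 without Wnt+ replicate 2. Immediate early and dissociation genes had a median of -0.31, and 0 of 24 passed when adjusted over the list alone (3 lower at an unadjusted limma p under 0.05). The list was lower in Wnt+ by its test (camera adjusted p = 9.86e-04, and adjusted p = 0.379 with an estimated correlation). In Notch signalling, 2 of 22 genes, the glycosyltransferases Mfng (-1.36) and Lfng (-0.98), fell when adjusted over the list alone (camera adjusted p = 0.0461, and adjusted p = 0.477 with an estimated correlation). The Notch call ended with 5 of the 7 arrays left out in turn (camera adjusted p of 0.00106 to 0.277). In TGF-beta and BMP signalling, 2 of 36 genes were higher and 3 lower when adjusted over the list alone, Smad1 (-0.90) and Tgfb1 (-1.36) among the latter (camera adjusted p = 0.353). In the extracellular matrix list, 3 of 32 genes were higher, with Col18a1 at 0.44, and 1 lower, Col4a1 at -0.60 (camera adjusted p = 0.660). In the cell cycle list, 1 of 30 genes was higher and 1 lower (camera adjusted p = 0.127). Of 32 cytosolic ribosomal proteins, 0 passed, and limma gave 0 at an unadjusted p under 0.05 (camera adjusted p = 0.656).

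In all, 16 of the 27 lists passed the camera test with its preset correlation, 11 higher and 5 lower in Wnt+. Some of the 27 lists share members, such as Shh in the zona glomerulosa and hedgehog lists, so their results are not independent. No list passed with an estimated correlation (lowest camera adjusted p = 0.285). By fry, which tests whether the members of a list move one way and compares the list with no other genes, 6 passed. These were both Wnt lists, the steroidogenic list, both zone lists and the lymphocyte list. In exact two-sided permutation tests of the list means, 10 lists reached the smallest p that the 35 splits of 7 arrays allow (0.0286). Their Benjamini-Hochberg adjusted exact p over the 27 lists was 0.0771.

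The authors' deposited table gives a fold change and an unadjusted p for each of 28944 transcript clusters in the same comparison. A p under 0.05 was listed for 3297 clusters in the authors' deposited table (1704 higher and 1593 lower in Wnt+) against 1447 from chance alone. A p under 0.01 was listed in the authors' deposited table for 829, of which 73 were at least 2-fold higher and 181 at least 2-fold lower. None of the p-values in the authors' deposited table passed 0.05 after Benjamini-Hochberg adjustment over all clusters, where limma on 1 cluster per gene gave 53 genes. The fold in the authors' deposited table was 2.93 for Nr5a1, 2.04 for Star, 2.00 for Cyp11a1 and 1.59 for Axin2, all as Wnt+ over SF1+.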

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

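The tests of explanations below were chosen after the results were seen, and so were the natural killer and plasmacytoid dendritic lists used in them.

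Among 133 gene and list values examined in the 4 SF1+ arrays, 4 had 1 array far from the other 3, where about 5% are expected by chance. In SF1+ replicate 1, Ptn was at 7.57 against 7.75 to 7.77 in the others, Cyp11b2 at 8.00 against 7.64 to 7.68, and Gata6 at 6.29 against 5.81 to 5.89. In SF1+ replicate 2, Dlk1 was at 4.18 against 5.09 to 5.25. In the authors' deposited table, the other experiment, Bio against vehicle, had 4636 transcript clusters at an unadjusted p under 0.01, where 289 are expected by chance, a signal outside the comparison of the sorts.

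Most lymphocyte, natural killer and interferon list members were lower in the libraries labelled Wnt+, but no immune or interferon list passed with an estimated correlation (lowest camera adjusted p over 31 lists = 0.172), and few macrophage and B cell markers moved (2 of 25 and 2 of 15 over the list alone). A lower share of cortical cells in the SF1+ sorts and nothing else would raise all other cell types alike there, but the chromaffin score was higher in Wnt+ by 0.896 (exact permutation p = 0.0286, the smallest the 35 splits allow). Endothelial markers did go with a lower cortical share, with all 25 negative and a score difference of -1.33. A candidate source is natural killer cells in the SF1+ sorts. Of 16 natural killer list members outside the called genes, 16 were also lower in Wnt+ at an unadjusted limma p under 0.05. Gzma fell from 6.97 to 3.52. Ccl5, at 8.81 in SF1+, was still at 6.94 and 7.12 in Wnt+ replicates 1 and 2, but at 3.54 in replicate 3. All 16 lymphocyte markers had a negative difference too. The T-cell genes Cd3d, Cd3g and Cd8a were at 0.347, 0.337 and 0.362 times their SF1+ values. The natural killer tally therefore does not tell these cells from T cells. For plasmacytoid dendritic cells the tally was 10 of 15, which leaves that source open. A perfect GFP gate would remove such cells unless they were autofluorescent, adherent to other cells or expressed the transgene. However, the macrophage and myeloid list mean was 6.84 to 8.54 in the SF1+ libraries and 6.69 to 7.47 in the Wnt+ libraries. Every library thus lay above the array medians for these markers, so neither gate can be taken to have removed all immune RNA. How complete the sorting was and a different response to interferon were not tested.

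Cortical genes were higher in the libraries labelled Wnt+, Nr5a1 included, though neither zone list passed with an estimated correlation (camera adjusted p = 0.285). If the SF1+ sorts held fewer cortical cells, zona fasciculata and zona glomerulosa scores should differ by like amounts, and the difference between these differences was 0.0433 (exact permutation p = 0.80), which 7 arrays could miss even if the zones differed. If the labels of the sorts had been exchanged, Nr5a1 should be higher in Wnt+, as its value of 1.55 is, but Wnt target genes should then be lower, and their score was higher (exact permutation p = 0.0286). With Nr5a1 short of the threshold, a smaller cortical share in SF1+, exchanged labels and a higher cortical expression in Wnt-responsive cells cannot be told apart.

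Of 23 chromaffin markers, 22 had a positive difference in the libraries labelled Wnt+, but 4 passed over the list alone and 0 over all genes, and the list passed neither with an estimated correlation (camera adjusted p = 0.379) nor by fry (adjusted p = 0.115). Of the 8 brightest chromaffin list members, 4 (Npy, Th, Scg2 and Pnmt) had every Wnt+ array above every SF1+ array, and Chgb, Chga, Dbh and Penk overlapped. Chromaffin cells in the Wnt+ sorts may account for this, but Chgb was already at 8.87 in SF1+, a level that would hide a small share, so both sorts may have held medullary RNA and the source stays open, as does Wnt activity in the medulla, which was not tested.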

How the results depend on the processing

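Leaving out both arrays nearest the other group and leaving out list members were chosen after the data were seen. All 53 genes kept their direction in each planned limma refit of single genes that tested them, but how many passed did not hold. As their arrays did not overlap between the groups, refits on the same values could not have changed a direction. Only median-centring, the further quantile normalisation and the mean of a gene's clusters could have done so. Leaving out 1 array at a time gave 1 to 312 genes (0 to 100 higher, 1 to 212 lower, 1 to 246 at least 2-fold), and the Wnt target list had an adjusted p of 0.0251 to 0.0585 and the steroidogenic list of 1.33e-04 to 4.54e-04. Deviations of same-numbered arrays from their group means had r of -0.217, 0.03 and -0.214 across genes, against -0.200 to 0.301 in other pairs. These values gave no sign of pairing, but 3 of them cannot exclude it. With a replicate block, on 6 or 7 arrays, 0 genes passed (0 higher, 0 lower, 0 at least 2-fold). At an unadjusted limma p under 0.05 there were 2468 genes, and the Wnt target list had a camera adjusted p of 0.0607. Genes passing, with those higher, lower and at least 2-fold, numbered 221 (61, 160 and 197) with dim genes left out, 27 (6, 21 and 24) after median-centring, 68 after a further quantile normalisation, 48 with the mean of a gene's clusters, 33 (6 and 27) with array weights, 155 (38, 117 and 132) with trended and robust moderation, 10 (2, 8 and 8) over all transcript clusters, 364 (129, 235 and 298) without SF1+ replicate 1 and Wnt+ replicate 1, and 4 (2, 2 and 4) without endothelial, immune and interferon list members, which were 15 of the 53. A threshold of 0.01 or a minimum change of 0.5 left 1 gene (0 higher, 1 lower, 1 at least 2-fold). Without moderation, or with the authors' p-values adjusted, 0 passed (0 higher, 0 lower, 0 at least 2-fold), against 2684 at an unadjusted p under 0.05 without moderation. With an estimated correlation 0 lists passed, the Wnt target and steroidogenic lists each at an adjusted p of 0.285, and fry passed 6; other settings gave 13 to 18 lists. Of the named genes, Gli1, not called, changed sign (-0.0028 without Wnt+ replicate 3, 0.14 without replicate 2), and called or uncalled values crossed the threshold downward 248 times and upward 43 times. Fewer arrays or fewer genes tested explain part of these shifts by construction; otherwise the cause was not tested. Lists with under 5 members above the median brightness gave no value with dim genes left out. Several lists without a call in the main test passed in 1 or more of the refits without an array. They were the hedgehog, X-zone, capsule, cholesterol uptake, cell cycle, extracellular matrix and ribosomal lists. Signal over background limits genes near the floor, such as Xist at 2.13 in these male mice.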

Other observations

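The 4 lists of immune cells and interferon genes and each test of a hypothesis below were chosen after the results were seen, while the splits of the arrays repeat the planned tests.

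Markers of natural killer, plasmacytoid dendritic and B cells were listed separately. All 20 natural killer markers were lower in Wnt+ when adjusted over the list alone, 4 of them over all genes, with a median of -1.74. Klrk1, an activating receptor, differed by -2.50 (SE 0.35), and the granzyme Gzmb by -2.82 (SE 0.60). Of 20 plasmacytoid dendritic markers, 13 were lower and 1 higher when adjusted over the list alone (median -1.04). Spib, a transcription factor of these cells, differed by -2.27 (SE 0.30), and Ly6d, which was at 9.08 in SF1+ and is thus bright in the sorted cells, by 0.64 (SE 0.12). Of 34 interferon-stimulated genes, 29 fell when adjusted over the list alone and 7 over all genes, among them Ifit3 (-2.03), Rsad2 (-1.90) and Bst2 (-1.13), with a median of -1.53. Of 15 B cell markers, 2 were lower when adjusted over the list alone, and the median was -0.13. With an estimated correlation, none of these lists passed when adjusted together with the 27 fixed lists (camera adjusted p over 31 lists = 0.172 for the natural killer, plasmacytoid and interferon lists and 0.288 for the B cell list). The natural killer list shares 3 members with other lists, the plasmacytoid list 3, the interferon list 2 and the B cell list 5, and how many of their genes the adrenal cortex expresses was not measured here, though 31 of the 34 interferon genes and 3 of the 20 natural killer genes lay above the median gene in Wnt+.

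Other splits of the 7 arrays into 3 and 4 were counted. Of the 35 splits, 1, the real one, gave as many genes: 53 against at most 6 in the others. It had 11 against 3 higher, 42 against 3 lower, and 38 against 6 at least 2-fold. These counts come from 1 fit and are not separate support. As 1 of 35 is the smallest share the splits allow (0.0286), a split by chance is made unlikely but is not excluded. For gene lists the real split gave 16 and the others 4 to 15, again 1 of 35, so the preset correlation called lists in every split. In the same permutation of the arrays, the steroidogenic list had a camera p of 4.21e-05 in the real split and 2.20e-04 at the most extreme of the others. That is 1 of 35 splits, the smallest share the splits allow, for 1 of 27 lists. The exact permutation p of its mean was 0.0771 when adjusted over the 27 lists, so chance is not excluded. In that permutation the Wnt target list had a camera p of 0.0158 in the real split and 0.0143 in another. As 2 of 35 splits were as extreme, chance cannot be excluded. That other split set SF1+ replicates 2, 3 and 4 against SF1+ replicate 1 and all Wnt+ arrays. It also gave the 6 genes and the camera p of 2.20e-04 for the steroidogenic list. The split with 15 lists set SF1+ replicates 1, 2 and 3 against SF1+ replicate 4 and all Wnt+ arrays. Both splits thus kept most of the real contrast.

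Wnt-responsive cells might be expected to differ from SF1+ cells more in Wnt targets than in steroidogenic genes, and the hypothesis was tested on the list scores. The Wnt target difference minus the steroidogenic difference was -0.40 (exact permutation p = 0.0286, the smallest the splits allow), the opposite sign. It was -0.45 among the 19 Wnt targets and 15 steroidogenic genes brighter than the median gene. That cut did not match the lists for brightness (whole-list means in SF1+ of 3.79 and 5.91). Compression of the dimmer Wnt targets is therefore not excluded. A second hypothesis was that genes the authors' deposited table lists as raised by Bio in tumor cell lines would be higher in Wnt+. For 396 such genes (p under 0.01 and at least 1.5-fold), the mean difference was 0.0622 (exact permutation p = 0.143), and for the 589 genes lowered by Bio it was -0.11 (exact permutation p = 0.171), so no difference was detected, although both signs go with Bio. In the authors' deposited table Bio raised Axin2 8.09-fold and Ccdc80 4.36-fold, with Apcdd1 at 0.498, Star at 0.270, Cyp11a1 at 0.534, Nr5a1 at 0.703 and Akr1c18 at 0.0516 times the vehicle value. The lists moved less than these genes. Of 35 Wnt targets, 7 were higher and 8 lower with Bio at the authors' paired p under 0.01 (median fold 0.950). Of 20 steroidogenic genes, 1 was higher and 5 lower (median fold 0.931).

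Nr6a1, the gene next to Nr5a1 in the GRCm38.p6 gene table, was singled out after its values were seen. It was at 8.06, 6.00, 5.73 and 7.37 in SF1+ replicates 1 to 4 and at 3.50, 3.73 and 3.61 in Wnt+ replicates 1 to 3, a difference of -3.18 (SE 0.56, limma adjusted p = 0.0855) that ranked 8 from the lowest of 20719 genes. The next measured neighbours differed by -0.41 (Nek6), 0.03 (Psmb7) and 0.51 (Olfml2a), none past the threshold. One hypothesis is that the Nr5a1 fragment that drives GFP in the SF1+ mice may carry part of Nr6a1, which would also argue against exchanged labels. The ends of the fragment are not given in the sources used here, and with the adjusted p above the threshold the hypothesis stays open.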
